A study of Neurospora crassa OR74A with 6 samples.

How the data were processed

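RNA was taken from 6 cultures of wild-type Neurospora crassa, 1 for each of 4, 8 and 16 h without and with chitosan, grown at 25 °C with shaking at 200 rpm under continuous light. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit from 1 µg of total RNA; whether the reads kept strand is not given in the sources used here. Per the submitters' processing notes, TopHat2 2.0.4, Bowtie2 2.0.0.6 and Cufflinks 2.0.2 were used. The genome build and gene annotation are not given in the sources used here, so no coordinates are printed. The authors deposited 3 tables, 1 per time point, each with the FPKM of 1 control and 1 chitosan library, a log2 fold change, an adjusted p-value and a test status per gene. Per the file headers and the labels, columns were matched to samples by the library number that each sample's description carries. The authors' adjusted p-values are reported as counts of genes only, since they come from 1 library per condition.

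Each table held 9839 rows for 9674 genes. The 165 repeated rows carried identical values and were collapsed, and 59 loci were merged entries of more than 1 gene. FPKM of merged or overlapping genes, of near-identical copies and of antisense pairs are uncertain, because reads cannot be assigned to 1 gene. Symbols came from a table of gene names for assembly NC12, which matched 9131 IDs and gave symbols for 1102; product names came from the deposited tables. Neither a symbol nor a product name was found for 5061 genes. Values of 0 are described as listed at 0.

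Depth could not be recovered. Among genes below 1 FPKM in both libraries of a table (1144, 1260 and 1157 genes), the most frequent ratio between the libraries was shared by only 0.874%, 0.714% and 0.605%, so no steps of whole reads were visible. FPKM were used as deposited, with a pseudocount of 1, and a gene was compared at a time when it had 5 FPKM or more in at least 1 of the 2 libraries. Genes at least 2-fold higher or lower on this scale were counted. With 1 library per group no test was run within a time. An effect common to the 3 times was tested with limma on the log2 ratios of the 3 times, which is the same as a model of log2(FPKM + 1) with time as a block and treatment. It leaves 2 residual degrees of freedom before the variances are moderated along a trend with mean level. The p-values are two-sided and Benjamini-Hochberg adjusted. Comparisons of levels between times cross tables that were normalized separately.

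Before the data were examined, 33 gene lists were fixed as patterns on symbols and product names and as a few IDs. For each list the median log2 ratio, the number of members beyond 2-fold and the percentile of the median among 10000 random lists of the same size, matched on deciles of mean FPKM, were computed as a description of the 2 libraries. Intervals of list medians are 95% binomial order-statistic intervals over members. Matching was case-blind at first and was made case-sensitive, as the patterns were written, once the list sizes had been seen. Pattern matching brought some members with other functions into lists, such as al-1 among the desaturases and eas among the light response genes. The genes named follow a rule fixed at the same point. At each time it took the 10 highest and 10 lowest log2 ratios among genes with a symbol or informative product name, and up to 4 members per list with the largest absolute ratio. It added up to 5 genes per direction that changed at least 2-fold the same way at all 3 times, and up to 2 IDs per direction and time for genes without a product name. Genes outside the rule are said to be chosen after their values were seen; a gene the rule named at 1 time is also given at others.

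Alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, no minimum or a minimum of 20 FPKM, libraries rescaled to a sum of 1000000, unweighted TMM factors (trimming 30% of log ratios and 5% of mean levels), ratios centred on their median, and the authors' calls with a 2-fold change. Equal sums and TMM for the lists, equal sums for the overlaps, the limma test and all its alternatives, subtraction of the median of each gene length decile, and lists trimmed of members with other functions were added after seeing the data. Gene lengths, from the table of gene names, were found for 95.8% of the 7172 genes compared at any time. The calculation was tested on simulated data: in each comparison, with noise of 0.25 log2 units, 100 genes changed 4-fold and 100 changed 8-fold were all counted as 2-fold changed. The genes changed all had 5 FPKM or more in control, so the test does not speak for genes near or below that level. Changes of 4-fold or more pass a 2-fold limit almost by construction at this noise. The test therefore checks the calculation, not the reliability of the counts. For limma, common changes were put into the residuals of the real ratios shuffled over genes. Of these, 5 of 100 genes changed 4-fold and 47 of 100 changed 8-fold were called, and 0 of 5725 unchanged genes. Shuffling within each time gives all genes the same spread of errors and removes correlation between genes. The 0 calls among unchanged genes therefore do not speak for false calls in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with R 4.3.3 and limma 3.58.1, were used.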

Results

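Messenger RNA of Neurospora crassa, a filamentous fungus grown from conidia (asexual spores), was measured by RNA sequencing in 6 libraries. Wild-type strain FGSC2489 was grown for 4, 8 or 16 h in Vogel's salts diluted 100 times with 2% sucrose, either without addition (control) or with chitosan at 0.5 µg per ml. Chitosan is a polymer made by removing acetyl groups from chitin, and this dose had been chosen by the submitters because it inhibited germination by 50%. Each of the 6 combinations of treatment and time had 1 library, so no difference within a time has a replicate check and no spread between cultures can be stated. The deposited values were FPKM for 9674 genes. The sum of FPKM was 775591 in control and 570342 with chitosan at 4 h, 767999 and 699865 at 8 h, and 508502 and 1031860 at 16 h. Read depth is unknown, so no counting interval accompanies any value. A difference is given as log2((chitosan FPKM + 1)/(control FPKM + 1)), called the log2 ratio, with both levels in FPKM, and this ratio understates the change of genes with low values. Within a time, "higher" and "lower" describe these 2 libraries and rest on no test.

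The question at each time was which genes differed between cultures grown from conidia with and without chitosan. Since the dose inhibited germination by 50%, the 2 cultures of a time may differ in the share of conidia germinated. That share is not given for these cultures, and its effect cannot be told apart from other effects of chitosan. At 4 h, 1185 of the 6818 genes compared were at least 2-fold higher with chitosan and 1670 were at least 2-fold lower. At 8 h the numbers were 753 higher and 1271 lower of 6481, and at 16 h they were 1506 higher and 1694 lower of 6392. The balance of higher against lower genes depended on how the libraries were scaled. The median log2 ratio over all genes compared was -0.19 at 4 h, -0.28 at 8 h and -0.13 at 16 h. Rescaling each library to an equal sum moved these medians by 0.42, 0.13 and -0.98, TMM factors by 0.04, 0.12 and 0.14, and centring by 0.19, 0.28 and 0.13. With equal sums, 64.9% of the 2-fold genes at 4 h were higher, against 41.5% as deposited, and at 16 h 16.6% were higher, against 47.1%. With ratios centred on their median the share higher was 51.8% at 4 h and 55.1% at 8 h, against 41.5% and 37.2% as deposited. In the authors' deposited table, an adjusted p below 0.05 marked 222 genes at 4 h (143 higher), 212 at 8 h (119 higher) and 252 at 16 h (45 higher).

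**Figure D1:**
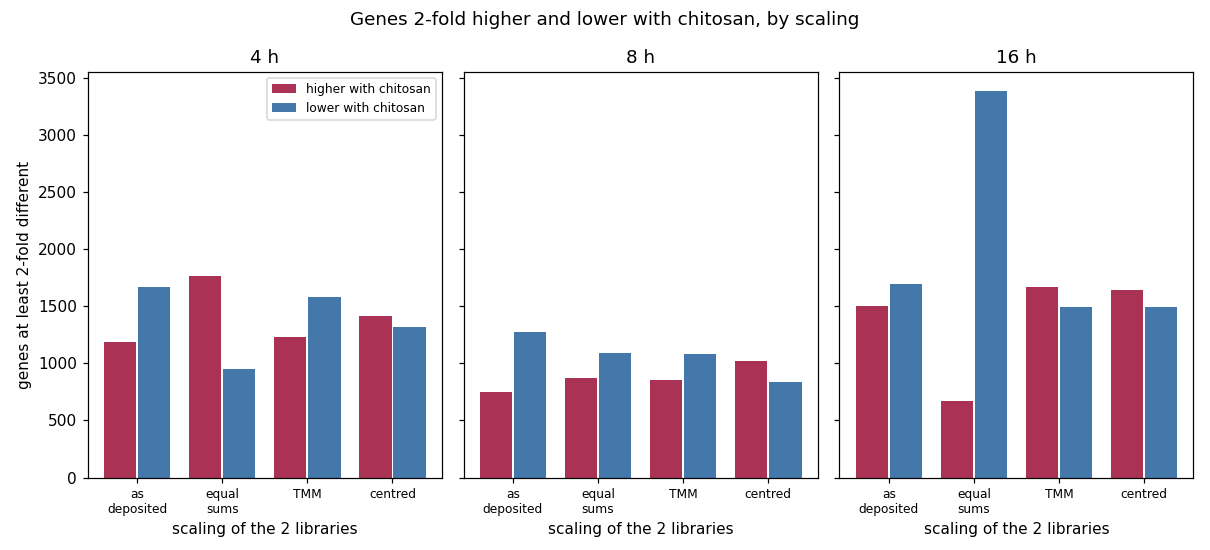
Bars give the number of genes at least 2-fold higher (red) or lower (blue) with chitosan at 4, 8 and 16 h, on the values as deposited and after 3 rescalings of the 2 libraries of each time, with 1 library per group. At 16 h the split was 1506 higher and 1694 lower as deposited, and 672 higher and 3385 lower with libraries of equal sums.

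The genes with the largest ratios after 4 h with chitosan mostly had low control values. NCU01849, an extracellular dioxygenase, stood at 3.28 and 7524 FPKM in control and chitosan, the largest log2 ratio among genes with a product name or symbol (10.78). The gene ccg-16 (NCU05495), whose product has a CVNH domain, was the most abundant transcript of the chitosan library at 17107 FPKM, against 201 FPKM in control. NCU03213, annotated as a mannosylphosphorylation protein, stood at 0.585 and 259 FPKM, log2 ratio 7.36. A pair of RTA1 domain proteins, NCU05649 and NCU02363, had log2 ratios of 6.12 and 5.76. Other genes among the 10 highest were NCU07898 (endoglucanase IV, 6.19), NCU06400 (amidohydrolase, 5.49), NCU10500 (F-box domain protein, 4.85), NCU03388 (stomatin family, 4.82) and NCU00984 (von Willebrand domain protein, 4.79). Of genes without a product name, NCU05277 (8.10) and NCU11664 (7.47) were highest.

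The lowest ratios at 4 h belonged to NCU06327, a benzoate 4-monooxygenase cytochrome P450 (442 and 4.87 FPKM, log2 ratio -6.24), NCU07610, a taurine dioxygenase (-5.28), and NCU04122, a malate dehydrogenase (1181 and 33.4 FPKM). They were followed by the mating response gene poi-2 (NCU05768, -4.92) and NCU06110, the thiazole enzyme of thiamine synthesis (1052 and 43.3 FPKM, log2 ratio -4.57). The 10 lowest also included rds1 (NCU05143, -4.42), the oxidoreductase mig-4 (NCU09040, -4.35), NCU07821 (dimethylaniline monooxygenase, -4.32), NCU07723 (norsolorinic acid reductase, -4.31) and con-8 (NCU09235, -4.27). Among genes without a product name, NCU11172 (-6.61) and the merged locus NCU12021,NCU12022 (-6.08) were lowest.

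Lists of protein synthesis and energy metabolism genes had medians below the random lists at 4 h. Of 79 cytosolic ribosomal protein genes measured, 69 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.26. That median stood at percentile 0 among 10000 random lists of the same size, matched only on deciles of mean FPKM. In the ribosome biogenesis list (nucleolar and rRNA processing proteins), 46 of 55 genes were lower, with a median of -1.64. Respiratory chain and ATP synthase genes had a median of -0.98, with 31 of 67 lower, among them atp-2 (NCU05430, 2479 and 680.1 FPKM) and cytochrome c, cyc-1 (NCU01808, 1478 and 391 FPKM). The glycolysis and fermentation list had a median of -0.94 (15 of 31 lower), the cell cycle and DNA replication list -0.76 (19 of 43) and the sterol list -0.70 (11 of 31). These 3 medians lay at percentiles 0.410, 0.585 and 2.00. In the list of genes needed for hyphal fusion, 8 of 16 were lower (median -1.15), including ham-8 (NCU02811, -3.64) and ham-7 (NCU00881, -2.64).

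The chitin and glucan, ABC transporter, proteasome and glyoxylate lists had medians above the random lists at 4 h, with members of the chitin, ABC and glyoxylate lists going both ways. The 95% intervals over members spanned both signs for chitin and glucan (-0.18 to 1.06), ABC transporters (-0.63 to 1.51) and the glyoxylate list (-0.12 to 0.52). The median over all genes compared was -0.19, so a median near no change can lie above the random lists. The list of chitin and glucan synthesis and remodelling had 19 of 53 genes at least 2-fold higher and 8 lower, with a median of 0.45 at percentile 99.9. It included the endochitinase gh18-5 (NCU04554, 36.8 and 573 FPKM), while the wall glucan-modifying gene gel-1 (NCU01162, 38.7 and 2.57 FPKM) was lower. Of ABC and multidrug transporters, 9 of 19 were higher and 3 lower (median 0.64), led by NCU03776 (2.25 and 71.9 FPKM) and NCU04021 (8.43 and 57.8 FPKM), while NCU05226 was lower (-1.64). The calcium and ion transport list had a median of 0.19 at percentile 95.5, inside the limits of the random lists, with 10 of 41 genes higher and 4 lower. In it the Na or K P-type ATPase ph7 (NCU08147, 3.57), the plasma membrane calcium ATPase nca-2 (NCU04736, 55.2 and 463 FPKM) and the sodium/calcium exchanger NCU02826 (2.75) were higher, and the potassium channel subunit NCU02887 (109 and 22.1 FPKM) was lower. Proteasome genes had a median of 0.39 at percentile 98.5, with 1 of 29 at least 2-fold higher. In the list of proteases and vacuolar degradation (median 0.07), 22 of 84 genes were higher and 15 lower, with vacuolar protease A, pep4 (NCU02273, 237 and 1437 FPKM), among the higher. The glyoxylate cycle, fatty acid oxidation and gluconeogenesis list had 11 of 58 genes higher and 8 lower, with a median of 0.19 at percentile 97.9.

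In the phosphate and nitrogen list at 4 h, the nitrate genes were lower, with nit-6 (NCU04720, nitrite reductase, -4.16), nit-3 (NCU05298, nitrate reductase, 202 and 12.3 FPKM) and nit-10 (NCU07205, nitrate transporter, -3.37), while the phosphate permease pho-4 (NCU09564) was higher (2.69). The median of that list was -0.30 as deposited and 0.13 with libraries of equal sums. In the conidiation list, con-8, con-6 (NCU08769, -2.96) and the hydrophobin gene eas (NCU08457, 6977 and 409 FPKM) were lower and ccg-16 was higher, and the median was -0.07 as deposited and 0.37 with equal sums. The carotenoid gene al-1 (NCU00552, phytoene desaturase) stood at 89.0 and 6.92 FPKM in the light response list, whose median was -0.46, and al-3 (NCU01427) of the same list was higher (1.56). Among oxidative stress genes, the mitochondrial peroxiredoxin rhd (NCU06031, -2.50), catalase-3 (cat-3, NCU00355, -2.04), sod-1 (NCU02133, -1.79) and NADPH oxidase nox-1 (NCU02110, -2.67) were lower, and the thioredoxin NCU00598 was higher (36.8 and 131 FPKM). The antioxidant list had a median of -0.23 as deposited and 0.21 with equal sums, and the flavin and NADPH oxidoreductase list one of -0.84 at percentile 2.73. Without members of other functions, the flavin median was -1.10 at percentile 0.970, below the random lists, with 6 of 11 genes lower. Heat shock proteins and chaperones had a median of -0.69, with hsp60 (NCU01589, -2.25) and hsp80 (NCU04142, -2.02) lower and the bcs1 chaperone NCU03921 (4.54) higher. Medians were -0.68 for glutathione S-transferases, -0.70 for MAP kinase and small GTPase signalling and -0.55 for amino acid transporters. They were -0.50 for cytochrome P450s and related monooxygenases, -0.45 for tubulin, actin and septins, and 0.15 for the secretory pathway. The -0.36 of sugar and other MFS transporters, -0.22 of cell wall and surface proteins, -0.14 of trehalose and osmotic stress, -0.14 of sphingolipid and phospholipid synthesis, -0.03 of secreted carbohydrate-active enzymes, -0.02 of metal transport and -0.01 of lipases and desaturases each turned positive with equal sums.

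Of the 10 genes with the largest ratios at 8 h, 5 were also among the 10 largest at 4 h. NCU01849 stood at 2.37 and 811 FPKM in control and chitosan (log2 ratio 7.91), NCU05649 at 3.54 and 380.3 FPKM and NCU00984 at 3.18 and 174 FPKM. Next came NCU01830, a 4-hydroxyphenylpyruvate dioxygenase of tyrosine breakdown (5.29), NCU02363 (4.84), NCU03213 (4.76) and NCU03921, annotated as the mitochondrial chaperone bcs1 (4.75). The last of the 10 were uricase, NCU07853, which acts in purine breakdown (8.61 and 255 FPKM), NCU01862 (SWIRM domain protein FUN19, 4.29) and kynureninase of tryptophan breakdown, NCU09183 (4.28). NCU11664 (6.30) and NCU04169 (5.58) were the highest genes without a product name.

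The 10 genes lowest at 8 h included conidiation, carotenoid and thiamine genes. The largest negative ratio was that of poi-2 (-6.90), followed by con-6 (579 and 8.80 FPKM) and nmt-1 (NCU09345), a thiamine biosynthesis gene, at 4361 and 113 FPKM. NCU06110, the other thiamine gene, stood at 8666 and 324 FPKM. The 10 lowest also held rds1 (-5.19), al-1 (234 and 5.63 FPKM), con-8 (-5.15), fkr-3 (NCU04371, a peptidyl-prolyl isomerase, -4.67), eas (3977 and 172 FPKM) and con-10 (NCU07325, 707 and 29.9 FPKM). Of genes without a product name, NCU08770 (-6.54) and NCU05712 (-6.11) were lowest. The light response and carotenoid list had 11 of 21 genes lower and 0 higher, with a median of -1.54 at percentile 0. It included al-2 (NCU00585, phytoene synthase, -4.19) and bli-4 (NCU08699, -3.90). The conidiation list was split, with 7 genes higher and 5 lower of 22, and its median of 0.57 went the opposite way from its con genes and eas.

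Proteasome genes moved together at 8 h. Of 29 measured, 21 were at least 2-fold lower and 0 higher, with a median of -1.10 at percentile 0.0200, against 0.39 at 4 h. Examples were rpn-7 (NCU03972, 103 and 35.6 FPKM) and NCU02493 (186 and 68.4 FPKM). Respiratory chain genes had a median of -0.69 with 28 of 67 lower, and the NADH dehydrogenase subunit genes nuo21.3a (NCU08930, -2.36) and nuo21 (NCU05221, -2.25) were lowest. Medians below the random lists were found also for flavin and NADPH oxidoreductases (-1.02, percentile 0.420), glutathione S-transferases (-1.09, percentile 1.48), glycolysis and fermentation (-0.67, percentile 2.01) and cell fusion (-0.79, percentile 2.16). The ribosomal lists no longer had genes 2-fold lower. Cytosolic ribosomal proteins had a median of 0.12 with none of 79 beyond 2-fold, and ribosome biogenesis had a median of 0.45 with 5 of 55 higher.

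Besides the ribosomal protein (percentile 100.0), ribosome biogenesis (100.0) and conidiation (100.0) lists, the chitin and glucan, ABC transporter and calcium lists had medians above the random lists at 8 h, again with members going both ways. In the chitin and glucan list, 12 of 52 genes were higher and 9 lower (median 0.30, percentile 100.0), with gh18-5 at 14.9 and 193 FPKM and the glucanosyltransferase gene gel-4 (NCU07253) at 23.7 and 203 FPKM, and with gel-1 lower (-2.99). Of ABC and multidrug transporters, 7 of 18 were higher and 3 lower (median 0.39, percentile 99.4), including NCU07546 (8.15 and 71.0 FPKM) and NCU05591, a CDR4-type transporter (2.18). The calcium list held NCU01504, a calcineurin binding protein (88.8 and 1005 FPKM), and nca-2 (23.8 and 227 FPKM), and had 8 of 38 genes higher and 5 lower. Its median was 0.09 at percentile 98.6, and -0.12 when only genes with 20 FPKM or more in 1 library were kept. The nitrate genes nit-10 (-4.50) and nit-3 (174 and 7.46 FPKM) were lower, and pho-5 (NCU08325, inorganic phosphate transporter, 3.83) was higher. Catalase-3 (162 and 11.8 FPKM) and cat-1 (NCU08791, -2.35) were lower. The os-2 kinase of the osmotic stress pathway (NCU07024) stood at 269.8 and 55.8 FPKM and mak-2 of the fusion pathway (NCU02393) at 409.6 and 110.4 FPKM.

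The remaining medians at 8 h lay between the limits of the random lists. They were -0.68 for phosphate and nitrogen supply, -0.59 for the secretory pathway, -0.54 for amino acid transporters and -0.51 for cytochrome P450s and related monooxygenases. Trehalose and osmotic stress had -0.48, the glyoxylate cycle list -0.46 and sterol synthesis -0.43. Tubulin, actin and septins had a median of -0.43, MAP kinase signalling -0.40, secreted carbohydrate-active enzymes -0.40, lipases and desaturases -0.37, and sphingolipid synthesis -0.35. Antioxidant enzymes stood at -0.34, cell cycle genes at -0.31 and heat shock proteins at -0.30. The medians of proteases (-0.20), sugar transporters (-0.17), metal transport (-0.16) and cell wall proteins (-0.13) turned positive with ratios centred on their median. The metal transport median depended on its members: without those of other functions it was 0.60 at percentile 99.9, above the random lists, with 4 of 17 genes higher and 2 lower. Secondary metabolism had 2 genes measured at 4 h (median 0.35), only pks-2 (NCU05011, 1.43) at 8 h and none at 16 h.

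At 16 h the direction of the ribosomal genes was the opposite of that at 4 h. Of 79 cytosolic ribosomal protein genes, 77 were at least 2-fold higher with chitosan and 1 lower, with a median log2 ratio of 3.35 as deposited and 2.33 with equal sums. For example, crp-5 (NCU04552) stood at 748 and 13218 FPKM in control and chitosan, and NCU06661, a 60S protein gene, at 385 and 9645 FPKM. Ribosome biogenesis had 50 of 55 genes higher (median 1.83, 0.88 with equal sums), including the nucleolar protein nop-58 (NCU03396, 20.8 and 222 FPKM). Of heat shock proteins and chaperones, 24 of 42 were higher and 3 lower (median 1.49, 0.54 with equal sums), with hsp60 at 15.1 and 244 FPKM, hsp80 at 32.5 and 458 FPKM and a chaperonin, NCU04334, at 33.7 and 797 FPKM. These 3 lists were above all 10000 random lists. Respiratory chain genes had 33 of 66 higher, among them the alternative oxidase aod-1 (NCU07953, 9.26 and 192 FPKM) and cyc-1 (160.2 and 2548 FPKM), but their median of 0.87 turned to -0.14 with equal sums. The 16 h ratio also varied with gene length. In the decile of shortest genes (median 1091 bp) the median ratio was 0.55 and in the decile of longest (5158 bp) it was -0.84, against 0.01 and -0.16 at 4 h and -0.36 and -0.04 at 8 h. With the median of each length decile subtracted, the ribosomal protein median was 3.04.

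The 10 genes with the largest ratios at 16 h did not follow their lists in every case. The monosaccharide transporter NCU04537 had the largest ratio of genes with a product name or symbol, although most genes of its list were lower (0.669 and 414 FPKM, log2 ratio 7.96), followed by the invertase gene inv (NCU04265, 1.51 and 131 FPKM) and the aldehyde dehydrogenase NCU09648 (5.34). The glutathione S-transferase genes gst-1 (NCU05780, 4.52 and 209 FPKM) and gst-4 (NCU10521, 5.20) were also among the 10 highest. The 8 genes of that list had a median of -0.27, with 3 at least 2-fold higher and 1 lower. The others were NCU03092 (nuclear localization sequence binding protein, 5.21), the fatty acid desaturase NCU09497 (4.76 and 204 FPKM), the lipase NCU03639 (5.09), the hexose transporter NCU01633 (23.8 and 750.1 FPKM) and the neutral amino acid permease mtr (NCU06619, 9.94 and 286 FPKM). NCU05134 (7.43) and NCU05908 (5.22) were the highest without a product name. The sterol gene erg-1 (NCU04156) had a ratio of 3.43, and the nitroreductase NCU03696 stood at 4.57 and 129.7 FPKM.

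The 10 genes lowest at 16 h included several taurine dioxygenases and nutrient transporters. The taurine dioxygenases NCU07819 (1998 and 1.94 FPKM, log2 ratio -9.41), NCU07610 (2022 and 8.83 FPKM) and NCU02196 (425 and 1.22 FPKM) were joined by NCU07820, a pantothenate transporter (-8.67). The pheromone gene ccg-4 (NCU02500) stood at 2524 and 9.56 FPKM, the amino acid permease NCU07129 at 1419 and 6.09 FPKM and eas at 10621 and 60.3 FPKM. The remaining genes of this set were NCU09904 (glucan 1,3-beta-glucosidase, -7.44), NCU07821 (-7.20) and poi-2 (-7.15). NCU07751, without a product name, was at 201 FPKM in control and listed at 0 with chitosan, and NCU09039 had a ratio of -6.73.

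At 16 h, 10 lists had medians below the limits of the random lists. Amino acid and peptide transporters had 13 of 21 genes lower (median -1.69, percentile 0), and sugar and other MFS transporters 28 of 52 lower and 8 higher (median -1.06, percentile 0.0200). Cytochrome P450s and related monooxygenases had 16 of 27 lower (median -1.49), and in that list NCU05340, an alkanesulfonate monooxygenase, stood at 414 and 3.83 FPKM. The light response and carotenoid list had 16 of 21 lower (median -1.46), with al-1 at 1391 and 134 FPKM. Of conidiation genes 11 of 21 were lower and 5 higher (median -1.12, percentile 0.100), including con-6 (429 and 21.2 FPKM). Without members of other functions the median was -1.96, with 11 of 18 lower and 3 higher. Cell fusion genes had 10 of 16 lower (median -1.43), led by ham-9 (NCU07389, -3.53) and ham-5 (NCU01789, -3.12). The chitin and glucan list, with positive medians at 4 and 8 h, had 22 of 51 genes lower and 3 higher (median -0.78, percentile 0.460), including the glucanase neg-1 (NCU04395, 51.2 and 0.759 FPKM). The others were MAP kinase signalling (-0.95, percentile 0.575), sphingolipid synthesis (-0.66, percentile 2.28) and cell wall proteins (-0.54, percentile 0.700). The potassium transporter hak-1 (NCU00790) stood at 433 and 9.45 FPKM, nit-10 at 323 and 4.89 FPKM and cat-1 at 666 and 64.2 FPKM, while the phosphate transporter NCU07375 (3.61), the thioredoxin NCU03714 (2.95) and the superoxide dismutase NCU07386 (2.89) were higher.

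Other lists had 16 h medians inside the limits of the random lists. ABC transporters stood at -0.81, secreted carbohydrate-active enzymes at -0.80, phosphate and nitrogen supply at -0.57, the glyoxylate cycle list at -0.24, tubulin, actin and septins at -0.24, and metal transport at -0.18 (-0.93 at percentile 2.77 without members of other functions). The medians of antioxidant enzymes (0.41), glycolysis and fermentation (0.34), lipases and desaturases (0.10), the proteasome (0.06), secretory pathway (0.04) and proteases (0.04) were positive as deposited and turned negative with equal sums. Those of flavin oxidoreductases (-0.02), cell cycle (-0.03), trehalose and osmotic stress (-0.07), sterol synthesis (-0.09, but 0.28 without members of other functions) and calcium transport (-0.11) were negative as deposited and positive with centred ratios. Over the 3 times, 37 of 97 list medians lay outside the central 95% of random lists, where 4.85 would be expected of random lists. Lists that share genes or regulation are not independent. Random lists reflect the sampling of genes within 1 pair of libraries and not the spread between cultures. The excess is therefore no test of an effect of chitosan.

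**Figure D2:**
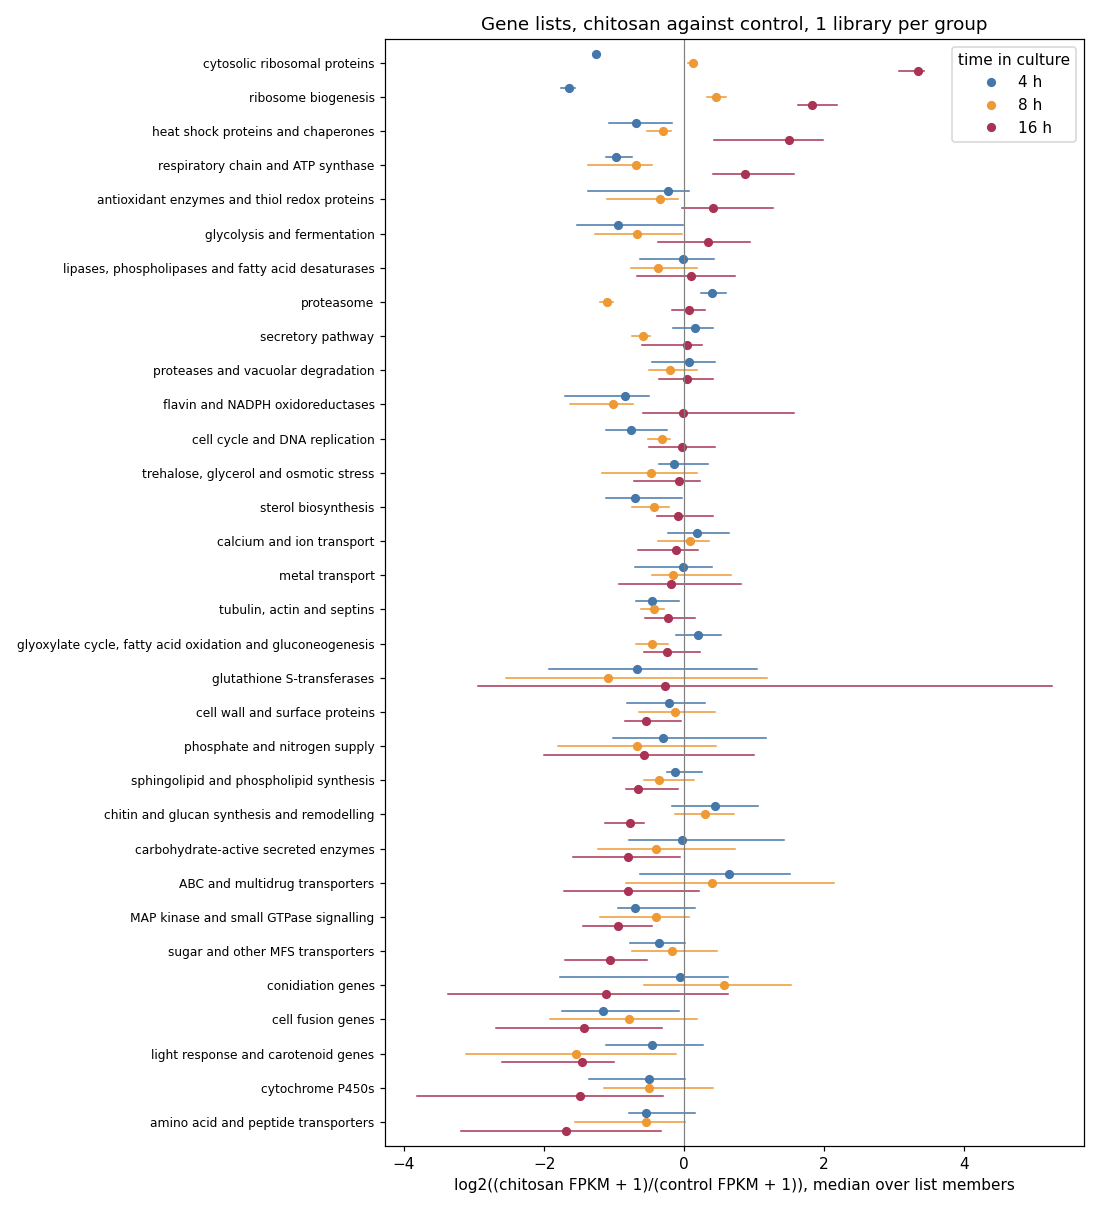
Points give the median log2 ratio of FPKM, chitosan over control, of each gene list at 4 h (blue), 8 h (orange) and 16 h (red), and lines give the 95% interval of the median over list members, which is not a replicate error. Cytosolic ribosomal proteins moved from -1.26 at 4 h to 3.35 at 16 h, and the proteasome list stood at -1.10 at 8 h, with the 16 h respiratory and proteasome medians, among others, changing sign when libraries were rescaled to equal sums.

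The 3 comparisons share no library, so their overlap can be set against that of independent lists. Of genes compared at 4 and 8 h, 544 were higher at both times, where 114 would be expected of independent lists, and 645 were lower at both, against 310 expected. Only 7 were higher at 4 h and lower at 8 h, and 23 the reverse. Between 4 and 16 h, 149 genes were higher at both (214 expected) and 395 lower at both (388 expected), while 717 were lower at 4 h and higher at 16 h (372 expected). That last number depended on scaling and was 232 with libraries of equal sums (92.8 expected). Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.69 for 4 and 8 h, -0.04 for 4 and 16 h, and 0.25 for 8 and 16 h. Spearman's rho for the same pairs of times was 0.54, -0.16 and 0.17. At all 3 times 112 genes were higher and 292 lower. From the genes shared by 4 and 8 h and the share changed at 16 h, 99.3 and 145 would be expected. As deposited, the lower genes therefore exceeded this number by far more than the higher ones. With libraries of equal sums 52 genes were higher at all 3 times. The numbers expected under that scaling were not computed, so the contrast holds only for the deposited values.

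An effect of chitosan common to the 3 times was tested with limma, with time as a block, on the 5925 genes compared at each time, a test added after the data were seen. With Benjamini-Hochberg adjusted p below 0.05, limma called 98 genes, 21 higher and 77 lower with chitosan, and 772 had an unadjusted p below 0.05. The number called depended on the setting, with 1 higher and 15 lower at a pseudocount of 10, 5 and 32 with length decile medians subtracted, and 5 and 41 without the 8 h pair. The test takes differences between the times as its error, so it passes over genes that responded at 1 time only. Among the genes called were poi-2 (mean log2 ratio -6.32, adjusted p 0.0181), the nitrate genes nit-3 (-4.18), nit-6 (-4.01) and nit-10 (-4.55), and con-8 (-4.49), con-6 (-4.37) and al-1 (-4.01) on the lower side. The RTA1 domain proteins NCU05649 (5.06) and NCU02363 (4.71), pho-5 (2.86) and NCU03921 (3.76) were called on the higher side. No cytosolic ribosomal protein, ribosome biogenesis or proteasome gene was called, over all genes or adjusted over the list alone. The phosphate and nitrogen list had 4 of 19 genes called over all genes tested (1 higher and 3 lower) and 6 adjusted over the list alone. The list of cytochrome P450s and related monooxygenases had 2 (lower) and 8 of 23. No gene called over all genes was annotated as a cytochrome P450, while the dimethylaniline monooxygenases NCU10387 and NCU07821 were called lower. The conidiation list had 2 (lower) called over all genes and 6 of 21 over the list alone. Some lists had none called over all genes but several adjusted over the list alone. Among them were cell fusion (6 of 16), secreted carbohydrate-active enzymes (6 of 23) and chitin and glucan (7 of 49). The adjustment over a list alone was made separately in each list, with no correction over the 33 lists. Its counts were not split by direction, and chitin and glucan genes such as gel-4 (higher) and gel-1 (lower) went opposite ways at all 3 times. These counts are therefore no support for a change of a list as a whole.

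Among the genes with the same direction at all 3 times, ranked by the smallest of their 3 ratios, most at the top had no product name. On the higher side NCU05134 had log2 ratios of 4.03, 5.12 and 7.43 at 4, 8 and 16 h, and NCU05202 had 4.84, 3.97 and 3.94. They were followed by NCU02363, the RTA1 domain protein (3.53 at its lowest, 16 h), NCU05555 (3.05 at 16 h) and NCU09355 (67.7 and 531 FPKM at 16 h). On the lower side were NCU03863 (-4.96, -5.42 and -5.76), poi-2, NCU11172 (806 and 30.2 FPKM at 16 h), NCU06140 (-4.49 at 16 h) and NCU05712 (-4.23 at 16 h). All of these except NCU09355 were among the genes limma called. Because limma tests the same 3 ratios by which these genes were ranked, the calls are no separate support.

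**Figure D3:**
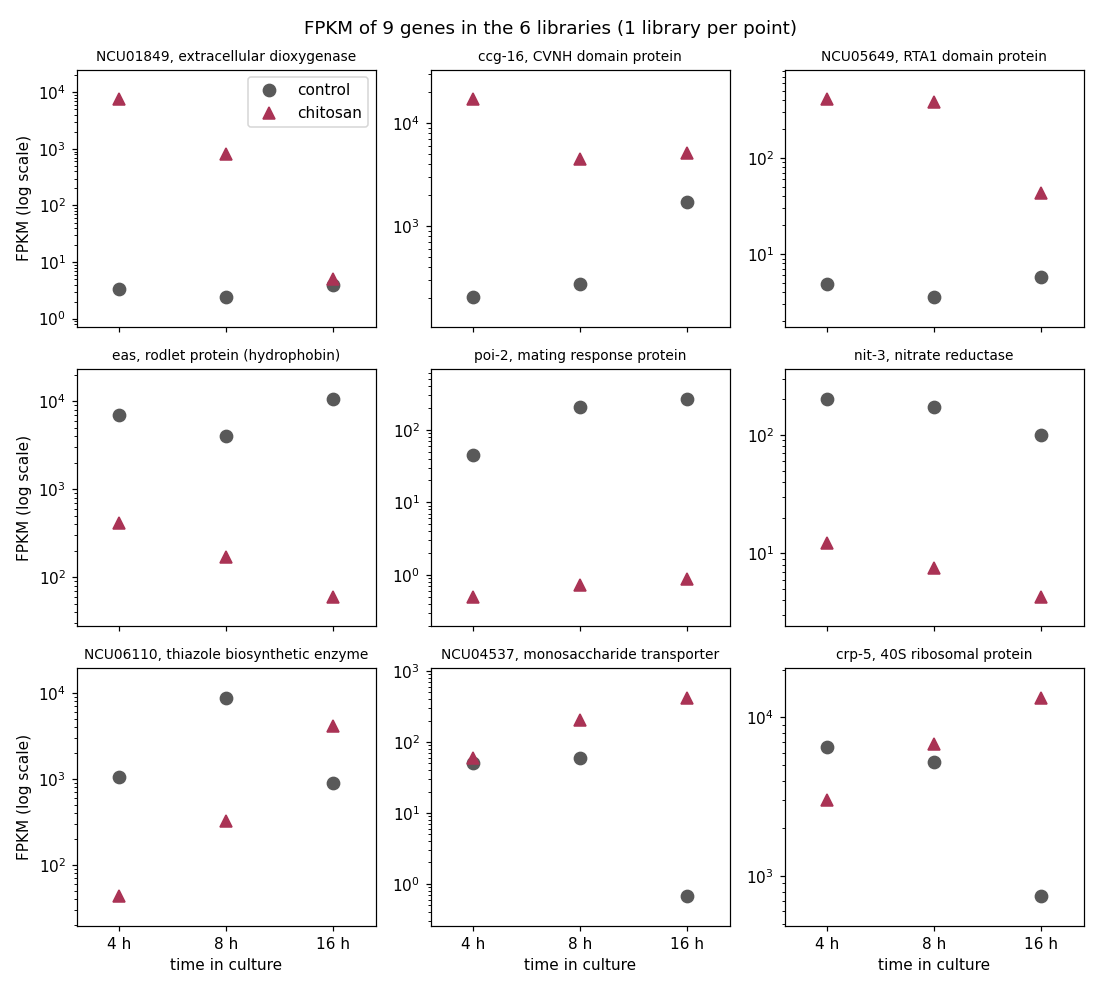
Each point is the FPKM (log axis) of 1 gene in 1 library, control (grey circles) or chitosan (red triangles), at 4, 8 and 16 h; the 3 tables were normalized separately, so levels are compared within a time. NCU01849 stood at 3.28 and 7524 FPKM in control and chitosan at 4 h, eas and poi-2 were lower with chitosan at each time, and NCU06110 was lower at 4 and 8 h and higher at 16 h.

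The untreated cultures changed with time as well, which gives a scale for the chitosan ratios, although the tables were normalized separately. Between control 4 and 8 h, 171 genes were 2-fold higher at 8 h and 468 lower, fewer than the chitosan comparison of either time. Between control 8 and 16 h, 919 were higher at 16 h and 1731 lower, but 1654 and 965 with equal sums, so the direction of this change depends on scaling. Cytosolic ribosomal protein genes had a median log2 ratio of -0.03 in control 8 h over 4 h and of -2.46 in control 16 h over 8 h, and ribosome biogenesis genes had -0.56 and -1.79. In the control 16 h library the clock-controlled gene ccg-1 (NCU03753), chosen after its value was seen, reached 62820 FPKM, 12.4% of the sum, against 12412 FPKM with chitosan.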

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

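The tests in this part were chosen after the results were seen, except that centring the ratios was fixed before, and none of the differences between times was tested, since each time has 1 library per group. A list or a gene of the 10 highest or lowest is given here when it was at least 2-fold higher with chitosan at 1 time and at least 2-fold lower at another, with no sign change under the 3 rescalings.

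Among the 33 lists this was so for cytosolic ribosomal proteins, whose median differed by 4.61 between 16 and 4 h, and ribosome biogenesis, whose median differed by 3.47. Among 47 genes it was so for 8. The thiamine genes NCU06110 and nmt-1 were lower at 4 and 8 h and higher at 16 h, with differences of 6.76 and 6.92 for NCU06110 and of 4.80 and 7.46 for nmt-1. The desaturase NCU09497 differed by 7.68 between 16 and 4 h. NCU03092, lower at 4 h, differed by 2.72 at 8 h and 6.86 at 16 h. The genes NCU01830, NCU01862, NCU03388 and NCU10500 were higher at 4 and 8 h and lower at 16 h. Their differences of 16 h from 4 and 8 h were -6.41 and -7.33 for NCU01830, -6.79 and -6.40 for NCU01862, -6.67 and -5.24 for NCU03388, and -6.06 and -4.07 for NCU10500.

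The higher ribosomal genes at 16 h are the first pattern weighed. The 3 rescalings tried do not account for it, because the ribosomal protein median was 2.33 under the one that lowered it most. The ribosome biogenesis median came to 0.88 there, below 2-fold, so scaling bears more on that list. With length decile medians subtracted, the ribosomal protein median was 3.04. The 2-fold limit used for this judgement was set with the values known. Equal sums moved the median over all genes by -0.98 and the shortest decile had a median of 0.55. A median of 3.35 could therefore hardly have come below the limit. A length effect stronger on ribosomal genes than on others of their length is not excluded. Exchanged 16 h libraries are argued against by genes changed 4-fold the same way at 4 and 8 h: of those also 2-fold changed at 16 h, at least 66.2% kept their direction under every scaling (83.7% as deposited). That set was chosen with the data known, and all 2-fold genes give a mixed answer: between 8 and 16 h, 196 and 447 genes kept their direction and 122 and 179 changed it, but between 4 and 16 h, 149 and 395 kept it and 274 and 717 changed it. With equal sums, 98 and 676 kept it and 307 and 57 changed it between 8 and 16 h, and 66 and 378 kept it and 829 and 232 changed it between 4 and 16 h. It stays open whether the chitosan culture was at an earlier stage than the 16 h control or the 16 h control library was itself unusual, and these cannot be told apart with 1 control library at 16 h. The 16 h chitosan library differed 2-fold at 2160 genes from the 8 h control and at 3200 from the 16 h control, and under the scaling with the highest share the first count was 72.6% of the second. The 16 h control, however, also stood apart from the 4 h control (2922 genes), the 8 h control (2650) and the 4 and 8 h chitosan libraries (3013 and 2984). Its ribosomal protein levels were the lowest of the 6 libraries, with medians of the other 5 over it of at least 0.78 under every scaling. The 16 h chitosan library stood 0.70 and 0.68 above the 4 and 8 h controls as deposited, and this lead changed with scaling. Over the 16 h control, the 4 h control, 8 h control and 16 h chitosan libraries had medians of 1.87, 1.86 and 2.33 with equal sums. With TMM those medians were 2.09, 2.32 and 3.50. All of this crosses tables normalized separately, and RNA quality was not tested.

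The lower proteasome genes at 8 h are the second pattern, and rpn-4 (chosen after its value was seen), named after the yeast regulator of proteasome genes, was higher there (20.2 and 370.1 FPKM in control and chitosan, log2 ratio 4.13). The rpn-4 ratio was smaller at 4 h (155 and 512 FPKM, 1.72) and 16 h (8.30 and 25.4 FPKM, 1.51), where the proteasome medians were 0.39 and 0.06. Its chitosan value was higher at 4 h than at 8 h. The larger ratio at 8 h than at 4 h thus went with a lower control value, across tables normalized separately. The proteasome median was -0.82 under the rescaling nearest to 0 and -0.67 with length decile medians subtracted, and it was -0.97 with equal sums and -0.98 with TMM, so neither scaling nor length by itself accounts for its direction; the limit of -0.5 used for this judgement was set with the values known. A control 8 h library with high proteasome values is neither shown nor excluded. For it, the 8 h chitosan library had a proteasome median of only -0.38 over the 4 h control, and the 8 h control one of 0.69 over the 4 h control. Against it, the 8 h chitosan library had a median of -1.08 over the 16 h control and the lowest proteasome level of the 6 libraries (68.2 FPKM), and the 16 h control and chitosan libraries stood at 0.02 and 0.03 over the 8 h control. Such a library and an effect of chitosan cannot be told apart with 1 library per group and separate normalization.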

How the results depend on the processing

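Equal sums and TMM for lists, equal sums for overlaps, length subtraction, trimmed lists and the limma test with all its alternatives were chosen after seeing the data; the other alternatives were fixed before. The labels carry no replicate numbers, so no replicate could serve as a block, and the only pairing was by time, in the limma test. Read depth is unknown and limits low genes most. Except where a cause is given, the cause of a change was not tested. Results kept here means within 1.5 times for counts and inside the 95% interval over members for list medians.

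Of the counts of 2-fold genes, 36 of 54 alternative values stayed within 1.5 times. With a pseudocount of 10, which by construction shrinks ratios of low genes, the counts were 710 higher and 996 lower at 4 h, 400 and 645 at 8 h, and 780 lower at 16 h. A minimum of 20 FPKM, which leaves fewer genes, gave 478 higher at 8 h and 928 lower at 16 h. Equal sums gave 954 lower at 4 h, and 672 higher and 3385 lower at 16 h. Centring gave 833 lower at 8 h, and length subtraction 768. In the authors' deposited table, calls with a 2-fold change numbered 122 and 71 at 4 h, 98 and 89 at 8 h, and 39 and 190 at 16 h, higher and lower.

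For the 37 list medians outside the random lists' limits, 236 of 277 alternative values stayed within the interval, and 1 changed sign. Calcium and ion transport at 8 h was -0.12 with a minimum of 20 FPKM, and 0.37 centred. Some intervals are wide, such as -2.54 to 1.18 for glutathione S-transferases and -0.84 to 2.14 for ABC transporters at 8 h. Lists with varied members therefore pass easily, and the share kept does not measure stability. Cytosolic ribosomal proteins, whose interval is narrow, gave at 4, 8 and 16 h -1.07, 0.40 and 3.47 centred, -0.82, 0.25 and 2.33 with equal sums, -1.22, 0.24 and 3.50 with TMM, and -0.97, 0.53 and 3.04 with length subtracted. Ribosome biogenesis gave -1.27 and 1.24 at 4 and 16 h with a pseudocount of 10, -1.45 and 0.73 at 4 and 8 h centred, -1.23 and 0.88 at 4 and 16 h with equal sums, and -1.41 and 0.81 at 4 and 8 h with length subtracted. The proteasome at 8 h gave -0.996 with a pseudocount of 10, -0.82 centred, -0.97 with equal sums, -0.98 with TMM and -0.67 with length subtracted, and at 4 h 0.84 with equal sums and 0.73 with length subtracted. Respiratory chain genes gave -0.54 (equal sums) and -0.72 (length) at 4 h, and -0.41 (centred) and -0.40 (length) at 8 h. With equal sums at 16 h, medians were -1.64 for sphingolipid synthesis, -1.77 for chitin and glucan, -1.56 for cell wall proteins, -2.02 for sugar transporters and -1.96 for MAP kinase signalling, and at 4 h 0.62 for the glyoxylate list. Chitin and glucan at 16 h was -0.50 with a pseudocount of 10, and flavin oxidoreductases at 8 h -0.61 with length subtracted. Of other list medians, 391 of 446 alternative values stayed in their interval, and of named genes' log2 ratios 2186 alternative values moved by less than 1.5-fold and 450 by more.

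Overlaps changed with the number of genes counted. Genes higher and lower at 4 and 8 h numbered 271 and 327 with a pseudocount of 10, and 315 and 428 with a minimum of 20 FPKM. Genes higher and lower at all 3 times numbered 58 and 149, and 72 and 171, under the same settings. With equal sums, 426 were lower at 4 and 8 h, 52 higher at all 3 times, and 232 lower at 4 h but higher at 16 h, against 717 as deposited. In the control course, a pseudocount of 10 gave 90 higher and 179 lower at 8 h over 4 h, and 505 and 1085 at 16 h over 8 h. Centring gave 297 and 307 at 8 h over 4 h, and equal sums 1654 and 965 at 16 h over 8 h.

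The genes limma called for an effect common to the 3 times, 21 higher and 77 lower, numbered 1 and 15 with a pseudocount of 10 and 5 and 32 with length subtracted. With equal sums 4 were higher, and with centring 47 were lower. Without the 4 h pair limma called 57 and 158, without the 8 h pair 5 and 41, and without the 16 h pair 480 and 655; without the 4 h or the 16 h pair the error was pooled wholly over genes, so those counts rest on no error of the gene's own. Of the 4 splits with 1 library of each time on each side, 1, the real one, gave as many as 98 genes, and the highest of the others gave 0. The separation was smaller without adjustment. At an unadjusted limma p below 0.05, the real split had 772 genes and the split with the 16 h libraries exchanged had 596. The remaining splits had 169 and 13. With only 4 splits, a share under 0.05 cannot be reached.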

Other observations

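The groups of genes in this paragraph were formed after the data were seen, so their counts describe these libraries and are not independent evidence. Most genes for taking up and breaking down sulphur compounds were lower with chitosan at each time, with 12 of 15, 10 of 13 and 11 of 14 at least 2-fold lower at 4, 8 and 16 h and medians of -2.41, -1.38 and -2.55, and 1 was higher at 4 h. Thiamine biosynthesis genes had medians of -1.74, -0.81 and 1.58 over 5 genes. Genes for breaking down aromatic amino acids and purines had 7 higher and 4 lower of 15 at 8 h (median 0.96). At 4 h 6 were higher and 2 lower of 16 (median 0.36), and at 16 h 3 higher and 6 lower (median 0.31), that median turning to -0.70 with equal sums. All 3 RTA1 family genes measured were at least 2-fold higher at each time, with medians of 5.76, 4.84 and 2.68. The 2 mannosylphosphate transfer genes measured had medians of 6.06 at 4 h and 3.73 at 8 h, and neither reached 5 FPKM at 16 h.

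The authors' deposited table called few of the abundant genes that were higher at 16 h. Of genes at least 8-fold higher there, 8.70% of those with 200 FPKM or more in 1 library were called, and 33.8% of those below that level. Of genes at least 8-fold lower, 54.2% and 63.9% were called. At 8 h the shares were 94.7% and 78.2% for higher genes and 89.5% and 82.7% for lower ones, and at 4 h they were 54.3% and 69.3%, and 40.7% and 68.4%. The trend of the 16 h ratio with gene length stayed when ribosomal proteins were left out, with medians of 0.53 in the shortest decile and -0.84 in the longest.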
